A study of Mus musculus with 12 samples.

How the data were processed

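Total RNA of mouse embryonic stem cells was prepared with a column kit, depleted of ribosomal RNA and sequenced, per the labels' protocols. Per the submitters' processing notes, the tools named were STAR 2.7.9a and DESeq2, with the mouse build mm39. The deposited values were raw counts per gene, 1 file per library. Per the file headers they were made with featureCounts 1.6.3 on read pairs, with the strand option at 2, assignment to the feature of largest overlap and the Ensembl GRCm39 gene models of release 104. No normalization had been applied to them. Strand was used in the counting, so antisense partners were kept apart, whereas pairs that map to near-identical copies could be lost or split. Members of the Zscan4, Usp17l, Tcstv, Rhox and Hspa1 families are therefore uncertain. Each file held 55416 genes. Coordinates were taken from the files, and gene symbols and biotypes were matched by gene identifier to GENCODE M21, an annotation of the preceding build used for names alone. It named 52135 of the identifiers (94.1%) and 17860 of the genes tested.

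Libraries were grouped by the genotype and state in their titles, giving WT undifferentiated, C48S undifferentiated, WT RA and C48S RA with 3 libraries each. The titles, the genotypes and the protocol place all RA libraries at day 2, and the differing days in the treatment field were not used. Genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr (minimum count 10), TMM scaling, and a robust quasi-likelihood fit with a mean per group over all 12 libraries, which leaves 8 residual degrees of freedom. Of the genes counted, 17940 entered the test. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The contrasts were C48S against WT in each state, RA against undifferentiated in each line, and the interaction, the RA change in C48S minus that in WT. The RA response difference was taken over genes chosen by the mean of the RA changes of both lines, so that the choice favours neither line, and the RA axis used the same genes per library.

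The 25 gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) at a preset correlation of 0.01, again with an estimated correlation, and with fry, which asks whether the genes of a list move on balance one way and compares them with no other genes. Camera called 6, 7, 13, 16 and 9 of the 25 lists for C48S against WT before RA, C48S against WT after RA, RA in WT, RA in C48S and the interaction, of which 1, 5, 8, 11 and 3 held with an estimated correlation. A call lost that way need not reflect correlation among the members. For the ERK targets, for example, the estimate was -0.0109, below the preset. Chromosome medians were tested with camera and an estimated correlation. The contrasts, lists, tests, alternatives and the rule for naming genes were fixed before the data were examined, except those named as added or chosen later. That rule took, per comparison, Pou5f1, the 8 largest rises and falls among called protein-coding genes with a symbol, at least 1 CPM in the higher group and no overlap of the groups, and up to 4 members of each list with the smallest adjusted p. Every member could be named for a list with at most 5 calls, and members of a list could be named in other comparisons. Where the lower group had no count, the fold is given as a bound against a floor of 3 counts over the group, and with 1 to 3 counts as a ratio with its exact 95% counting interval.

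The procedure was tested on simulated counts with known changes. For C48S against WT before RA (17037 genes) it called 38, 86, 92 and 100% of genes changed 1.25-, 1.5-, 2- and 4-fold, and 7.60% of its calls were unchanged genes, somewhat above the threshold. After RA (17057 genes) it called 48, 82, 94 and 98%, and 6.94% of calls were unchanged. Each fold was given to 50 genes, far fewer than were called in the data, so these rates need not hold there. With an RA response scaled to 0.8 of that of WT, the RA response difference came out at -0.41 for an expected -0.40 (6905 genes), and with equal responses at 0.00106 (7730 genes). Both lines were given the same levels before RA, so lines that differ there, as in the data, were not tested. With the scaled response 90.6% of genes responded less in C48S, against 67.0% in the data. A list of 15 genes shifted by 0.5 on the log2 scale was found by camera, and an unshifted list was not. Alternatives were RLE scaling, DESeq2 1.42.0, other low-count filters, protein-coding genes alone, fits of the compared groups alone, a fold of 1.5 as the null, the replicate number as a block, and each library left out in turn. Leaving out chromosomes 6, 8, 11 and Y was added after seeing the data. Library totals lay between 8678088 and 13597098 counts, which measures abundant genes closely and leaves wide counting intervals for genes near 1 CPM. No library was left out. Some single genes are not reported here.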

Results

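RNA sequencing counts were available for 12 libraries of mouse embryonic stem cells of the Bl/6J line, which combine a genotype and a culture state. The genotype was either wild type (WT) or that of a clone in which the pluripotency transcription factor Oct4, the product of Pou5f1, carries the C48S change, a replacement of a cysteine by a serine. The titles do not say whether the WT cells are the parent of that clone. The state was either undifferentiated, with inhibitors of the kinases MEK (PD, 1 µM) and GSK3 (CHIR, 3 µM) and with ascorbic acid, or day 2 of retinoic acid (RA, 1.50 mg/L) without leukaemia inhibitory factor (LIF), the cytokine that sustains self-renewal. The labels do not say whether the inhibitors and ascorbic acid, an antioxidant and cofactor of TET enzymes, were kept during RA, so effects of RA and of the medium are not separated, the oxidative stress and TET lists included. Each of the 4 groups held 3 libraries, with total counts from 8678088 to 13597098 per library. The design asks how the lines differ before and after RA, and the series title names the redox sensitivity of Oct4 in reprogramming and differentiation. The mutant line is a single clone, number 46, so the mutation and any other property of that clone cannot be told apart here. The treatment field of the RA libraries gives a different day for each of them, from 2 to 7, whereas every title and the protocol give day 2, by which they were grouped. In that field the WT libraries carry days 2, 3 and 4 and the C48S libraries days 5, 6 and 7. Libraries of different days should differ, but those of a line after RA were about as alike as the WT undifferentiated libraries (chi-square per degree of freedom at most 1.93 in WT and 2.08 in C48S, against 1.94), which argues against that field. The labels do not say whether the libraries of a group come from separate cultures, so p-values measure the spread between these libraries, which may be technical.

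Libraries of a group correlated across genes at r = 0.988 or more. C48S undifferentiated replicate 3 stood apart from replicates 1 and 2, with a chi-square per degree of freedom of up to 9.38, against at most 2.08 within any other group. The principal component with 67.1% of the variance separated the states, and the next, with 19.3%, the lines. Changes are given as edgeR log2 fold changes ± SE from 3 libraries per group, and levels as mean CPM ± SD with n = 3, where CPM is the count scaled to the size of the library.

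Pou5f1, the mutated gene (ENSMUSG00000024406, chromosome 17, 35816915 to 35821669 on GRCm39), was at 587, 579 and 589 CPM in the WT undifferentiated libraries. In the C48S undifferentiated libraries it was at 512, 505 and, in replicate 3, 653 CPM, and the difference between the lines did not pass the test (-0.072 ± 0.071, adjusted p = 0.411). That rested on replicate 3, without which Pou5f1 was lower in C48S and passed the test (-0.20). After RA it was at 24.1, 22.0 and 22.8 CPM in WT, and at 71.5, 68.3 and 65.1 CPM in C48S, which was higher by 1.57 ± 0.098 (adjusted p = 7.99e-11). It fell with RA in WT (-4.67 ± 0.093) and in C48S (-3.03 ± 0.081), and the RA changes differed by 1.65 ± 0.12 (adjusted p = 2.12e-09). A point mutation leaves the transcript in place, so these levels do not check the genotype labels.

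**Figure D1:**
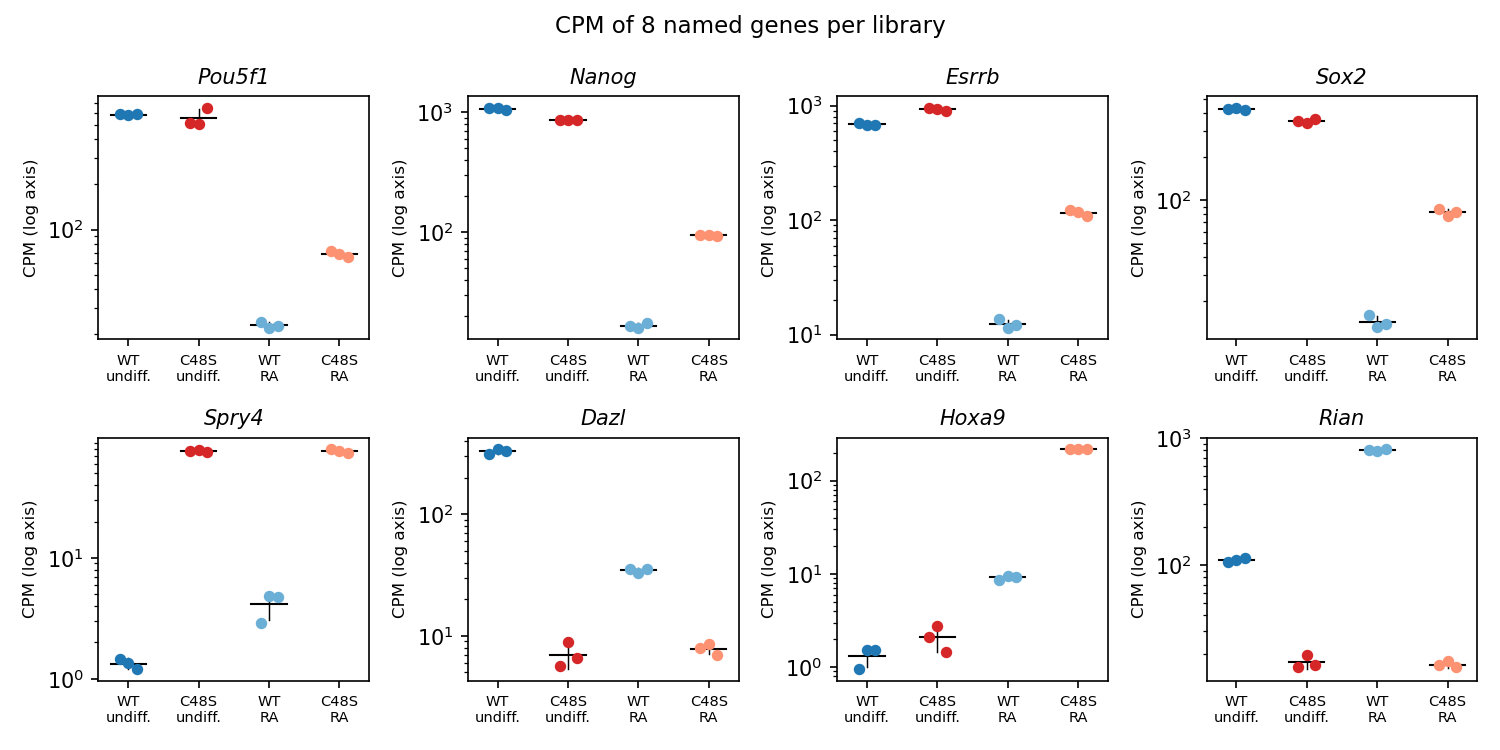
CPM (log axis) of 8 genes in each library, with 1 point per library, the group mean as a horizontal line and the SD as a vertical line. Pou5f1 was near 585 CPM in WT and 557 CPM in C48S before RA and at 23.0 and 68.3 CPM after it, while Rian was at 807 CPM in WT and 16.4 CPM in C48S after RA.

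Genes of chromosomes 6, 8 and 11 differed together between the lines, in both states. Over protein-coding genes with a mean of at least 1 CPM, the median log2 change of C48S against WT was 0.58 before and 0.63 after RA on chromosome 6 (659 genes, camera adjusted p = 7.76e-05 and 1.59e-05). On chromosome 8 it was 0.52 and 0.58 (739 genes, 2.92e-04 and 7.57e-05), and on chromosome 11 it was -0.53 and -0.48 (1167 genes, 4.45e-04 and 7.57e-05). Chromosome 16 was shifted slightly, by -0.15 and -0.11 (adjusted p = 0.0305 and 0.0145). The 8 genes of the Y chromosome had medians of -3.42 and -2.35 (0.0361 and 0.0190), and Zfy1, a Y-linked zinc finger gene, was at 24.6 ± 1.39 CPM in WT and 0.255 ± 0.225 CPM in C48S before RA. The Y genes did not move together. Before RA the log2 change was -0.30 for Uty and 0.60 for Gm47283. No other chromosome passed the test in either state. Together chromosomes 6, 8, 11 and Y held 3251 of the 17940 genes tested (18.1%), and 22.9% of the genes that differed between the lines before RA and 24.1% of those that differed after it.

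**Figure D2:**
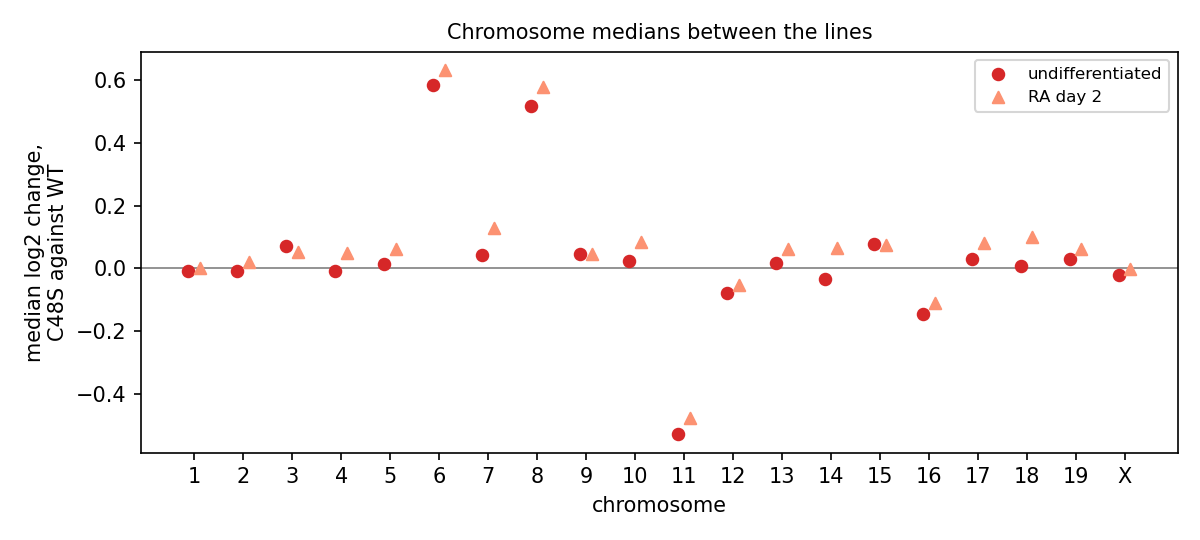
Median log2 change of C48S against WT over the protein-coding genes of each chromosome (at least 1 CPM on average), as circles for undifferentiated cells and triangles for RA day 2, without the Y and mitochondrial chromosomes. Chromosomes 6 and 8 lie at 0.52 to 0.63 and chromosome 11 at -0.53 and -0.48.

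Before RA, 2-cell-like transcripts were lower in C48S than in WT, and theirs was the 1 list of 25 that held with an estimated correlation. Dazl, an RNA-binding protein of germ cells, was at 330.2 ± 15.3 CPM in WT and 7.02 ± 1.73 CPM in C48S (-5.57 ± 0.089), and Spry4, a feedback inhibitor of receptor tyrosine kinase signalling, was at 1.33 ± 0.138 and 76.7 ± 1.46 CPM (5.83 ± 0.14). Dnmt3a, a de novo DNA methyltransferase, fell from 255 ± 4.18 to 50.6 ± 3.30 CPM (-2.33 ± 0.054). Among the genes with the largest rises were Epha1, an ephrin receptor on chromosome 6 (6.91 ± 0.27), the homeobox gene Nkx6-3 on chromosome 8 (6.88 ± 0.30), the forkhead factor Foxd1 (4.71 ± 0.15) and Pdyn, which encodes an opioid peptide precursor (4.92 ± 0.34). Ly6g6f was 124-fold (95% counting interval 21.9 to 4948) higher, Sel1l3 was 34.8-fold (95% counting interval 9.28 to 293) higher, and the homeobox gene Hmx2, without a count in WT undifferentiated cells, was at least 10.3-fold higher, taking 3 counts over the group as the floor. These intervals and floors cover counting error only. Genes without a count in C48S included Magea5, an X-linked gene of the MAGE family (at least 50.3-fold lower), Ccdc7a on chromosome 8 (at least 42.8-fold), the olfactory receptor gene Olfr316 on chromosome 11 (at least 35.8-fold), Lst1 (at least 21.5-fold) and the channel gene Pkd2l1 (at least 17.9-fold). Dcdc2a, of the doublecortin family, was 339.9-fold (95% counting interval 60.6 to 13466) lower.

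Of the 2-cell-like list, genes of the early cleavage embryo, 13 of 16 members fell and 0 rose (camera adjusted p = 8.89e-05, and adjusted p = 0.0272 with an estimated correlation). Most members belong to the Zscan4, Usp17l and Tcstv families of near-identical copies, so neither the count nor the test rests on separate genes. Tmem92 on chromosome 11 fell from 4.31 ± 0.274 to 0.264 ± 0.221 CPM, and Zscan4d (-3.25 ± 0.34) and Zscan4a (-2.58 ± 0.28) belong to a family of near-identical copies, so their single values are uncertain. In the germline list 11 of 18 fell and 2 rose (adjusted p = 0.00293, but adjusted p = 0.0508 with an estimated correlation), with Brdt, a testis bromodomain protein (-3.78 ± 0.14), Hormad1, a meiotic chromosome protein (-1.81 ± 0.097), and Tuba3a on chromosome 6 (-3.97 ± 0.11) lower. Of the ERK targets 9 of 14 rose and 3 fell, with a median of 1.06 (adjusted p = 0.00786, but adjusted p = 0.0747 with an estimated correlation). They included the transcription factor Etv4 (4.36 ± 0.10), which rose although it lies on chromosome 11, the phosphatase Dusp6 (1.94 ± 0.11) and the inhibitor Spred1 (1.64 ± 0.073). Of the Wnt targets 8 of 12 fell and 2 rose (median -0.84, adjusted p = 0.0125, but adjusted p = 0.0880 with an estimated correlation). The feedback gene Axin2 (-1.05 ± 0.057), the transcription factor Tcf7 (-1.02 ± 0.061) and the secreted inhibitor Notum (-1.11 ± 0.075) lie on the shifted chromosome 11, and the transcription factor Sp5 (-3.04 ± 0.13) lies on chromosome 2. Without genes on chromosomes 6, 8, 11 and Y the germline and Wnt lists lost their call (adjusted p = 0.0565 and 0.910).

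Of the formative and primed pluripotency genes 8 of 10 fell and 1 rose (median -0.74, adjusted p = 0.0125, but adjusted p = 0.183 with an estimated correlation), among them Dnmt3b (-1.35 ± 0.051) and the forkhead factor Foxd3 (-1.22 ± 0.11). Of the p53 targets 11 of 15 rose and 2 fell (median 0.42, adjusted p = 0.00509, but adjusted p = 0.183 with an estimated correlation), with the desmosome-associated Perp (2.28 ± 0.095) and the antiproliferative Btg2 (1.17 ± 0.064) higher and the nuclease Aen lower (-0.95 ± 0.061). The naive pluripotency genes went both ways, with 5 of 16 higher and 8 lower (adjusted p = 0.760): Klf4 rose (1.59 ± 0.052), whereas Prdm14 (-1.68 ± 0.079) and Dppa3 on chromosome 6 (-2.37 ± 0.13) fell. In the DNA methylation and TET enzyme list 6 of 10 rose and 3 fell (adjusted p = 0.760), with the cofactor Dnmt3l higher (1.21 ± 0.069). The epithelial-mesenchymal list had 3 of 12 higher and 6 lower (adjusted p = 0.757), and the unfolded protein and heat shock list 6 of 15 higher and 5 lower (adjusted p = 0.778), with the chaperone Hsph1 lower (-1.26 ± 0.045). Of the POU family 1 of 8 rose and 3 fell (adjusted p = 0.942), and Pou2f3 was the member that rose (1.78 ± 0.11). Of the fibroblast and feeder cell markers 9 of 16 rose and 3 fell (adjusted p = 0.0679). Col1a1, a fibrillar collagen, was at 143 ± 7.61 CPM in WT and 269.6 ± 56.1 CPM in C48S, whereas the proteoglycan Dcn fell from 45.8 ± 2.09 to 28.7 ± 2.25 CPM (-0.67 ± 0.092). The counts adjusted over the list alone were equal for these lists, except 15 lower for the 2-cell-like genes and 10 higher for the ERK targets.

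In all, 9970 of 17940 genes differed between the undifferentiated lines, 4932 higher and 5038 lower in C48S. By at least 2-fold 1437 were higher and 1788 lower. Against a fold of 1.5 as the null, 3605 genes passed, 1673 higher and 1932 lower, since with a biological coefficient of variation of 0.0549 differences well under 2-fold were called.

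RA in WT cells asks how the WT line responds to RA without LIF. Naive and general pluripotency genes fell, while most genes of the retinoid, Hox and trophoblast lists rose. Nanog fell from 1069 ± 22.1 to 16.6 ± 0.844 CPM (-6.01 ± 0.059), the nuclear receptor gene Esrrb from 685 ± 13.8 to 12.4 ± 1.06 CPM (-5.79 ± 0.068) and Tdh, the threonine dehydrogenase of mouse pluripotent cells, from 662 ± 16.6 to 1.09 ± 0.314 CPM (-9.25 ± 0.092). Cyp26a1, which degrades RA, rose 2504-fold (95% counting interval 857 to 12147) to 246 ± 10.6 CPM, and Hoxb1, a direct RA target, rose 1957-fold (95% counting interval 541 to 16165). All 16 naive pluripotency genes fell (median -3.80, adjusted p = 2.99e-09). Of the general pluripotency genes 13 of 15 fell and 2 rose (adjusted p = 1.26e-05), with the growth factor Fgf4 (-6.96 ± 0.09) and Sox2, the partner of Oct4 (-4.92 ± 0.067), lower. Of the RA response genes 17 of 19 rose and 1 fell (adjusted p = 1.36e-06), including Stra8, the trigger of meiotic entry (5.39 ± 0.069), the RA-binding protein gene Crabp2 (6.36 ± 0.12) and the homeobox gene Meis1 (6.56 ± 0.12). Of the Hox genes 36 of 39 rose and 2 fell (adjusted p = 3.80e-08), with Hoxb4 (4.92 ± 0.15) among those higher. Csn3, a casein gene without a count before RA, rose at least 137-fold, and Prdm14 was among the strongest falls (-8.06 ± 0.16).

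Of the lineage lists in WT, that of trophoblast genes held with an estimated correlation (adjusted p = 0.0245). Of the trophoblast genes 13 of 16 rose and 2 fell (median 2.73, adjusted p = 0.00233), with the keratin genes Krt8 (5.87 ± 0.11) and Krt18 (5.97 ± 0.10) higher, which other simple epithelia also express. The 2 that fell were Tead4 (-2.23 ± 0.10) and the homeobox gene Cdx2 (-0.93 ± 0.21). The Rhox members of the list are uncertain as near-identical copies. Of the endoderm genes 16 of 18 rose and 1 fell (adjusted p = 5.30e-04, but adjusted p = 0.0508 with an estimated correlation). Of the neuroectoderm genes 12 of 16 rose and 2 fell (adjusted p = 0.0338, but adjusted p = 0.132 with an estimated correlation). The laminin gene Lamb1 (1.51 ± 0.048), the collagen gene Col4a2 (2.11 ± 0.072) and the neural regulator Pax6 (3.86 ± 0.28) rose, and the neuronal tubulin gene Tubb3 fell (-4.79 ± 0.15). Of the mesoderm genes 8 of 13 rose and 3 fell (adjusted p = 0.160), and of the formative and primed pluripotency genes 3 of 10 rose and 5 fell (adjusted p = 0.269). All 16 2-cell-like genes rose (median 5.24, adjusted p = 1.54e-06), among them Zscan4d (5.09 ± 0.11, uncertain as above). Of the imprinted genes 19 of 25 rose and 5 fell (adjusted p = 3.48e-04, but adjusted p = 0.0733 with an estimated correlation), and Peg10 reached 8572 ± 123 CPM (6.79 ± 0.061) with Mest at 1183 ± 26.4 CPM (3.65 ± 0.052).

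Of the oxidative stress and NRF2 genes 19 of 22 fell in WT with RA and 1 rose (median -0.83, adjusted p = 2.62e-06), with glutathione reductase, Gsr (-2.89 ± 0.058), and the mitochondrial superoxide dismutase Sod2 (-2.87 ± 0.06) lower. Of the LIF-STAT3 targets 10 of 12 fell and 2 rose (adjusted p = 9.06e-04), with Klf4 (-3.60 ± 0.068) and Tfcp2l1 (-3.91 ± 0.056), both also in the naive list, and Pramel7 (-6.66 ± 0.16) lower. Of the oxidative phosphorylation genes 16 of 19 fell and 0 rose (median -0.60, adjusted p = 5.30e-04, but adjusted p = 0.289 with an estimated correlation). Of the G1-S and mitosis genes 14 of 20 fell and 6 rose (adjusted p = 0.0168, but adjusted p = 0.108 with an estimated correlation), such as the helicase subunit Mcm2 (-1.78 ± 0.045). The latter list lost its call without genes on chromosomes 6, 8, 11 and Y (adjusted p = 0.0894). The ERK targets went both ways, with 8 of 14 higher and 4 lower (adjusted p = 0.513): Dusp6 rose (3.88 ± 0.093) and Etv5 fell from 784 ± 13.4 to 33.4 ± 2.45 CPM (-4.55 ± 0.062). The counts adjusted over the list alone were equal, except 37 higher for the Hox genes. In all, 14054 genes changed in WT, 7345 up and 6709 down. By at least 2-fold 4781 rose and 2706 fell, and 9060 passed against a fold of 1.5, of which 5229 rose and 3831 fell. Scaling to the total cannot show a change in RNA per cell.

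In C48S cells, too, naive and general pluripotency genes fell with RA and without LIF, and retinoid, Hox, trophoblast and endoderm genes rose. Nanog fell from 858 ± 2.88 to 94.2 ± 0.891 CPM (-3.19 ± 0.048), Esrrb from 933 ± 30.7 to 116 ± 6.89 CPM, Sox2 from 355 ± 11.7 to 82.4 ± 4.70 CPM (-2.10 ± 0.053) and Tdh from 857 ± 20.9 to 10.2 ± 0.539 CPM (-6.40 ± 0.066). Cyp26a1 reached 536 ± 8.92 CPM (11.89 ± 0.13), and Hoxb1, without a count before RA, rose at least 1362-fold. The homeobox gene Lhx1 (at least 483-fold), Csn3 (at least 469-fold), the synaptic vesicle gene Syn2 (at least 48.2-fold) and the forkhead gene Foxl2 (at least 38.1-fold) rose likewise. Among the strongest falls were Khdc3, a maternal-effect gene (-6.97 ± 0.21), the AKT cofactor gene Tcl1 (-6.67 ± 0.18) and Foxd3 (-5.88 ± 0.23). All 16 naive pluripotency genes fell (median -2.97, adjusted p = 1.83e-09). Of the general pluripotency genes 12 of 15 fell and 3 rose (adjusted p = 3.91e-05). Of the RA response genes 16 of 19 rose and 1 fell (adjusted p = 1.73e-07), with the retinol transporter receptor Stra6 higher (7.57 ± 0.13). Of the Hox genes 37 of 39 rose and 1 fell (adjusted p = 5.18e-11), with Hoxa9 at 218 ± 1.62 CPM (6.69 ± 0.11).

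Of the trophoblast genes 14 of 16 rose in C48S and 1 fell (adjusted p = 1.16e-04), including the caudal homeobox gene Cdx2, which marks trophectoderm and posterior embryo (6.17 ± 0.22). Of the endoderm genes 16 of 18 rose and 2 fell (adjusted p = 1.39e-04), with the pioneer factor Foxa1 higher (5.21 ± 0.22). Of the mesoderm genes 8 of 13 rose and 2 fell (adjusted p = 0.0301, but adjusted p = 0.121 with an estimated correlation), with Wnt3a (2.97 ± 0.18) and Eomes (1.93 ± 0.15) higher. Of the formative and primed pluripotency genes 6 of 10 rose and 4 fell (median 1.32, adjusted p = 0.290). Of the neuroectoderm genes 12 of 16 rose and 2 fell (adjusted p = 0.0275, but adjusted p = 0.118 with an estimated correlation). All 16 2-cell-like genes rose (adjusted p = 1.47e-06). Of the germline genes 14 of 18 rose and 1 fell (median 1.53, adjusted p = 5.37e-04), among them Brdt (2.56 ± 0.16), the RNA helicase gene Ddx4 (1.28 ± 0.092) and Taf7l (3.47 ± 0.16). Of the oxidative stress and NRF2 genes 18 of 22 fell and 2 rose (adjusted p = 3.91e-05). Of the oxidative phosphorylation genes 18 of 19 fell and 0 rose (adjusted p = 1.74e-05, but adjusted p = 0.143 with an estimated correlation). Of the LIF-STAT3 targets 9 of 12 fell and 3 rose (adjusted p = 0.00316), with the feedback inhibitor Socs3 lower (-2.47 ± 0.072). Of the G1-S and mitosis genes 14 of 20 fell and 3 rose (adjusted p = 0.00147), with Pcna lower (-1.21 ± 0.047). Of the imprinted genes 16 of 25 rose and 5 fell (adjusted p = 0.00316, but adjusted p = 0.118 with an estimated correlation). Of the fibroblast markers 11 of 16 fell and 4 rose (adjusted p = 0.0139, but adjusted p = 0.0632 with an estimated correlation), and the starting level of Col1a1 was 269.6 ± 56.1 CPM in C48S. Without genes on chromosomes 6, 8, 11 and Y the mesoderm, imprinted and fibroblast lists lost their call (adjusted p = 0.343, 0.0601 and 0.0556). The counts adjusted over the list alone were equal, except 3 lower for the neuroectoderm genes. In all, 13203 genes changed in C48S, 6991 up and 6212 down. By at least 2-fold 4192 rose and 1617 fell, and 7032 passed against a fold of 1.5, of which 4522 rose and 2510 fell.

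After RA, the comparison of the lines asks how the mutant clone differs from WT at the same day of treatment, and naive and general pluripotency genes were higher in C48S. Esrrb was at 12.4 ± 1.06 CPM in WT and 116 ± 6.89 CPM in C48S (3.23 ± 0.07), Klf4 at 17.6 ± 1.22 and 119.5 ± 7.33 CPM (2.77 ± 0.069), and Nanog, on the shifted chromosome 6, at 16.6 ± 0.844 and 94.2 ± 0.891 CPM (2.50 ± 0.061). Of the naive pluripotency genes 11 of 16 were higher and 2 lower (median 1.17, adjusted p = 1.12e-04). Of the general pluripotency genes 13 of 15 were higher and 1 lower (median 1.23, adjusted p = 2.17e-07), including Sox2 (2.54 ± 0.071) and Tdgf1, a Nodal co-receptor (1.67 ± 0.059). Of the formative and primed genes 5 of 10 were higher and 2 lower (adjusted p = 0.185). Of the ERK targets 11 of 14 were higher and 1 lower (median 0.83, adjusted p = 6.08e-05), with Etv5 at 33.4 ± 2.45 and 174 ± 2.41 CPM (2.38 ± 0.062), Spry4 (4.19 ± 0.11), Spry2 (2.35 ± 0.092) and, on chromosome 11, Etv4 (3.09 ± 0.088). All 16 2-cell-like genes were lower (median -2.85, adjusted p = 2.85e-09), with Zscan4d at 109 ± 7.21 and 18.1 ± 1.45 CPM and Usp17le at 131 ± 2.82 and 13.1 ± 1.56 CPM, again uncertain as single genes.

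Of the Hox genes 24 of 39 were higher and 6 lower in C48S after RA (median 0.72, adjusted p = 0.00386), and the clusters lie on chromosomes that differ in their shift. The Hoxa genes, on chromosome 6, had a median of 1.93, with Hoxa9 (4.56 ± 0.084), Hoxa10 (4.02 ± 0.14) and Hoxa7 (2.95 ± 0.10) higher. The 10 Hoxb genes, on chromosome 11, had a median of -0.32, and 1 was higher and 4 were lower. Of the 9 Hoxc genes, on chromosome 15, 7 were higher and 2 lower, and of the 9 Hoxd genes, on chromosome 2, 5 were higher and 0 lower. The RA response list went both ways, with 8 of 19 higher and 8 lower (adjusted p = 0.992). Its median (0.0027) and mean (0.072) lay above 0, whereas the test, set against other genes, pointed down. Cyp26a1 (1.13 ± 0.05), Stra6 (1.21 ± 0.068) and the caudal homeobox gene Cdx1 (1.90 ± 0.065) were higher, and Stra8 on chromosome 6 was lower (-0.81 ± 0.048). Cdx2 was at 2.95 ± 0.962 and 38.2 ± 2.84 CPM (3.68 ± 0.16), whereas Krt18 was lower (-1.60 ± 0.067), and the trophoblast list had 4 of 16 higher and 8 lower (adjusted p = 0.328).

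Of the oxidative stress and NRF2 genes 15 of 22 were higher and 2 lower in C48S after RA (median 0.31, adjusted p = 0.00166, but adjusted p = 0.118 with an estimated correlation). Gsr (1.41 ± 0.06) and the haem oxygenase gene Hmox1 (1.28 ± 0.067) lie on the shifted chromosome 8, and Srxn1, which repairs peroxiredoxins (1.55 ± 0.081), lies on chromosome 2. Before RA that list had 6 of 22 higher and 7 lower (adjusted p = 0.942). Of the imprinted genes 14 of 25 were lower and 6 higher (median -0.41, adjusted p = 0.00398, but adjusted p = 0.180 with an estimated correlation): the noncoding RNAs Rian (-5.63 ± 0.066) and Meg3 (-5.21 ± 0.083) were lower, and the growth factor gene Igf2 was higher (3.98 ± 0.11). The glycolysis list had 8 of 16 higher and 3 lower (adjusted p = 0.0554), with the glucose transporter gene Slc2a3 on chromosome 6 (1.40 ± 0.044) and the phosphofructokinase gene Pfkp (1.45 ± 0.055) higher. Among the largest differences were higher levels of Ffar3, a receptor for short-chain fatty acids (6.26 ± 0.32), the proneural gene Neurog1 (4.69 ± 0.24) and Nkx1-2 (4.46 ± 0.32), and lower levels of Usp26, an X-linked deubiquitinase gene (-5.42 ± 0.098), and Zfy1 on the Y (-6.00 ± 0.25). The serotonin receptor gene Htr5a was 72.5-fold (95% counting interval 19.8 to 604) higher, and Rerg, on chromosome 6, was 38.2-fold (95% counting interval 12.8 to 188) higher. The fibroblast markers had 2 of 16 higher and 6 lower (adjusted p = 0.496), with Col1a1 at 74.9 ± 5.14 and 78.2 ± 3.59 CPM. The counts adjusted over the list alone were equal to these. In all, 9785 genes differed, 5168 higher and 4617 lower in C48S, and 2952 passed against a fold of 1.5. By at least 2-fold, 1108 were higher and 1467 lower. The larger side depended on the scaling, with 4629 higher and 5072 lower under RLE and 4065 and 4496 with DESeq2. It also turned without WT undifferentiated replicate 1 (4912 and 4936), 2 (4901 and 4909) or 3 (4902 and 4921), C48S undifferentiated replicate 2 (5012 and 5026) or WT RA replicate 3 (4432 and 4462).

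Of the genes that differed between the lines in either state, 6456 differed in both, 5156 of them (79.9%) in the same direction and 1300 in opposite directions. Both times higher were 2739 genes, against 1421 for independent lists, and both times lower were 2417, against 1297. Fisher's exact test across genes, which are not independent replicates, gave an odds ratio of 2.56 (p = 2.10e-208), and the comparisons share no library. The odds ratio depended on the genes tested and the tool, with 7.78 without a low-count filter and 4.86 with DESeq2. Dnmt3a, for example, was lower in C48S before RA and higher after it (0.79 ± 0.05).

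The interaction asks whether the RA change differs between the lines, and is positive where C48S rose more or fell less. Cdx2 fell from 5.70 ± 0.786 to 2.95 ± 0.962 CPM in WT and rose from 0.523 ± 0.323 to 38.2 ± 2.84 CPM in C48S, an interaction of 7.10 ± 0.33. That of Nanog was 2.82 ± 0.075, that of Sox2 2.82 ± 0.087 and that of Esrrb 2.78 ± 0.086. Of the naive pluripotency genes 12 of 16 had a positive and 0 a negative interaction (median 1.21, adjusted p = 5.98e-07). Of the general pluripotency genes 13 of 15 were positive and 2 negative (median 1.19, adjusted p = 7.62e-06), with Sall4 positive (1.40 ± 0.063) and the RNA-binding protein gene Lin28a negative (-1.58 ± 0.079). Of the germline genes 13 of 18 were positive and 1 negative (median 1.26, adjusted p = 9.54e-05), including Brdt (3.73 ± 0.19), Dazl (3.43 ± 0.15) and, on chromosome 6, Tuba3a (3.10 ± 0.18) and Stk31 (1.88 ± 0.15), which started lower in C48S. Dnmt3a fell in WT (-1.29 ± 0.05) and rose in C48S (1.83 ± 0.054), an interaction of 3.12 ± 0.074, and of its list of formative and primed genes 7 of 10 were positive and 1 negative (adjusted p = 1.12e-04, but adjusted p = 0.0561 with an estimated correlation), with Nodal positive (1.66 ± 0.09).

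Of the oxidative stress and NRF2 genes 12 of 22 had a positive and 1 a negative interaction (adjusted p = 0.00453, but adjusted p = 0.108 with an estimated correlation), with the peroxidase gene Gpx4 (1.08 ± 0.07) and Srxn1 (1.39 ± 0.12) positive, neither on a shifted chromosome. Of the Wnt targets 7 of 12 were positive and 1 negative (adjusted p = 0.00567, but adjusted p = 0.0561 with an estimated correlation), among them Lef1 (1.37 ± 0.12) and Notum (1.88 ± 0.15). Among the ERK targets, Etv5 (2.66 ± 0.079) and Spry2 (2.73 ± 0.11) were positive and Etv4 negative (-1.27 ± 0.15), with 4 of 14 positive and 6 negative (adjusted p = 0.652). Of the imprinted genes 5 of 25 were positive and 10 negative (adjusted p = 0.0159, but adjusted p = 0.241 with an estimated correlation), with Rian (-2.95 ± 0.10) and Peg10 on chromosome 6 (-1.95 ± 0.07) negative. Krt8 (-2.95 ± 0.17) and Krt18 (-2.06 ± 0.18) were negative. Of the fibroblast markers 1 of 16 was positive and 8 were negative (adjusted p = 0.0101, but adjusted p = 0.0661 with an estimated correlation), such as Col1a2 on chromosome 6 (-2.32 ± 0.16) and Col5a1 (-0.91 ± 0.11). Without genes on chromosomes 6, 8, 11 and Y the Wnt, imprinted and fibroblast lists lost their call (adjusted p = 0.0629, 0.134 and 0.0621). The 2-cell-like list moved below other genes as a set (adjusted p = 0.0159, but adjusted p = 0.0661 with an estimated correlation). The smallest adjusted p of a single member in edgeR was 0.0538, for Tmem92 (1.14), which passed with an interaction of 1.96 without C48S undifferentiated replicate 3, 1.19 without WT RA replicate 1 and 1.20 without C48S RA replicate 2. The counts adjusted over the list alone were equal for these lists, except 9 positive for the Wnt targets and 5 positive for the ERK targets. In all, 7071 genes had an interaction, 3990 positive and 3081 negative, and 2257 passed against a fold of 1.5, of which 1366 were positive and 891 negative.

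The RA response of C48S was smaller at the median over the genes that responded, but not at the medians of the RA response and Hox lists. In the RA response list 5 of 19 genes had a positive and 7 a negative interaction (median 0.30, camera adjusted p = 0.778). In the Hox list 9 of 39 were positive and 2 negative (median 0.36, camera adjusted p = 0.0665). Over 6595 genes chosen by the mean of their RA changes in the lines (adjusted p under 0.05 and a size of at least 1 on the log2 scale), the median difference of C48S from WT, signed along the direction of the response, was -0.38 with a jackknife SD of 0.0600. The median was -0.31 over the 4569 genes that rose, of which 61.4% responded less in C48S. It was -0.47 over the 2026 that fell, of which 79.5% responded less. With no limit on the size of the change, over 14800 genes, the median was -0.19. Of the genes with an interaction, 3904 changed less in C48S, 1328 changed more, and 1839 had changes of opposite sign. These are signs of the fitted changes, whether or not the RA change was called in each line. Of the 11454 genes called with RA in both lines, 10772 changed in the same direction and 682 in opposite directions. On the RA axis, the mean log2 CPM of the genes that rose minus that of the genes that fell, WT libraries moved from -4.12 ± 0.00660 to 0.0267 ± 0.00120 (SD, n = 3), and C48S libraries from -3.80 ± 0.0457 to -0.62 ± 0.0113. The span of C48S was 76.6% of that of WT. C48S lay above WT before RA by 0.33 and differed from it by -0.65 after RA (exact two-sided permutation p = 0.1 for each, the smallest that 3 against 3 libraries allow). Before RA the genes that fell were at a mean log2 CPM of 4.74 to 4.75 in WT and 4.41 to 4.46 in C48S libraries. After RA they were at 2.785 to 2.804 and 3.10 to 3.11. Their smaller fall in C48S therefore combines a lower level before RA with a higher level after it. The genes that rose began at 0.617 to 0.630 in WT and 0.608 to 0.652 in C48S.

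**Figure D3:**
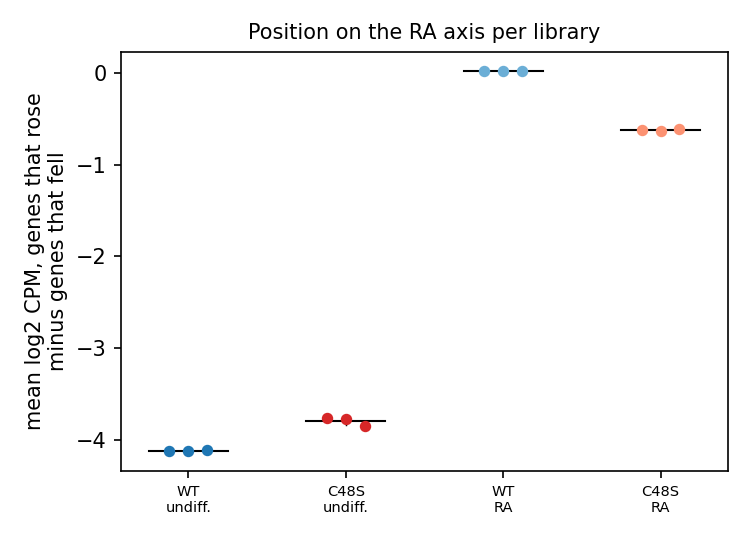
Position of each library on the RA axis, the mean log2 CPM of genes that rose with RA minus that of genes that fell, with 1 point per library, the group mean as a horizontal line and the SD as a vertical line. After RA the C48S libraries lie near -0.62 and the WT libraries near 0.0267.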

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

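Of the tests below, the one on a share of undifferentiated cells and the one on genes off chromosomes 6, 8, 11 and Y were chosen only after the result was seen. The RA response was smaller in C48S than in WT, with a median difference of -0.38 over 6595 genes, and the interaction called 7071 genes. For the genes that fell, part of the difference was a lower mean level in C48S before RA. Of 100 splits drawn from the 200 possible splits of the genotype labels within each state 1, the real one, gave a median as far from 0. The next was 0.31. Of the other draws, 85 mixed the lines in both states and 13 in 1 state, so differences between the lines entered their spread. These splits therefore cannot tell whether chance between cultures gave the difference. A share of C48S cells might have stayed undifferentiated among cells that responded as in WT. If they kept their levels, the same share of every strongly falling gene should be left. Over 26 such genes, chosen by their fall in WT, the share left ran from 1.42% to 13.8% (10th to 90th percentile, ratio 9.75), from Khdc3 at 0.790% to H2-M5 at 25.6%. This argues against such cells as the whole cause only if they kept their levels. RA was given without LIF, which could lower these genes unequally in cells that did not respond. A share of unresponsive cells therefore stays open. The median over genes off the shifted chromosomes was -0.38 as well, so the difference was not confined to those chromosomes. This says little on direct dosage of their genes, since a ratio alike in both states cancels in the RA change. The C48S mutation, effects of the shifted chromosomes on genes elsewhere, another property of the clone and a different rate of response also stay open. The design cannot separate them.

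For the 7071 genes with an interaction, 2 of 100 splits reached the real count. Besides the real one this was a split with 10909 genes, which exchanges the genotype labels in 1 of the states. It adds up the differences between the lines, which is a structure of the samples. The 85 draws that mixed the lines in both states called 0 genes, with the differences between the lines in their spread. The splits therefore cannot exclude chance for this count either.

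The RA change also differed between the lines, by the interaction test, for the naive pluripotency genes (median difference 1.21), the general pluripotency genes (1.19) and the germline genes (1.26). Camera called the germline list lower in C48S before RA. That call was lost with an estimated correlation (camera adjusted p = 0.0508) and without chromosomes 6, 8, 11 and Y (camera adjusted p = 0.0565). After RA the germline list had a median difference between the lines of 0.10 (6 of 18 higher and 4 lower, camera adjusted p = 0.992), with a mean of -0.058. For 17 of the 111 genes named, the RA change was called in both lines with opposite signs. The interaction was 7.10 for Cdx2, 6.46 for Ffar3, 3.73 for Brdt, 3.12 for Dnmt3a, 3.10 for Tuba3a, 1.88 for Stk31, 1.39 for Srxn1, 0.93 for Slc2a3, 0.74 for Aen and 0.71 for Axin2, all of which fell in WT and rose in C48S. Those that rose in WT and fell in C48S were Foxd1 (-4.83), Col1a2 (-2.32), Col5a1 (-0.91) and Dnmt3l (-0.89). The fitted values of Htr5a (8.87), Dcdc2a (7.10) and Lst1 (7.05) rest on a group with at most 3 counts, depend on the prior count and are no measure of size. No group was tested for a library far from the others, since each holds 3.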

How the results depend on the processing

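The fits without chromosomes 6, 8, 11 and Y and the alternatives of the RA axis were chosen only after the results were seen, and the others were planned. The counts of changed genes stayed within 1.5 times the reported ones under RLE scaling, DESeq2, other low-count filters, protein-coding genes alone, fits of the compared groups alone and the replicate block. For C48S against WT before RA they lay between 8847 (compared groups alone) and 10200 (no low-count filter). DESeq2 called 9161, 8561, 14198, 12726 and 6112 genes in the order of C48S against WT before and after RA, RA in WT, RA in C48S and the interaction. After RA more genes were higher than lower in C48S (5168 and 4617), but fewer under RLE scaling (4629 and 5072), with DESeq2 (4065 and 4496) and against a fold of 1.5 (1420 and 1532). Against a fold of 1.5 as the null the counts were 3605, 2952, 9060, 7032 and 2257, because small differences no longer counted. Without chromosomes 6, 8, 11 and Y, 7607, 7320 and 5701 genes were called before RA, after RA and for the interaction. Leaving out each library in turn gave 9189 to 10221, 8889 to 10737, 13687 to 14743, 12706 to 13381 and 6420 to 7771 genes. Without C48S undifferentiated replicate 3, which stood apart, they were 10221, 10737, 14743, 13247 and 7771. Replicate numbers did not pair the libraries: deviations of libraries with the same number correlated at -0.0529 to 0.0290, and 2 of 12 libraries correlated best with their own number. The replicate block gave 9858, 9638, 13969, 13092 and 6938 genes, 5075 shared calls and an RA response difference of -0.38, and changed no call of a list. The RA response difference lay between -0.41 and -0.34 with a library left out. It was -0.51 over genes with a mean RA change of at least 2 and -0.19 with no size limit, where weakly responding genes entered. The RA axis difference after RA was -0.58 with no low-count filter and -0.66 without the shifted chromosomes; the cause was not tested. Shared calls in the same direction were 4392 to 5144, with odds ratios from 2.48 (RLE scaling) to 7.78 (no low-count filter). Lists that passed fry in the direction opposite to that of camera, none of them called by camera, were DNA methylation before RA (fry adjusted p = 9.95e-06, down), RA response after RA (0.00164, up) and germline with RA in WT (6.29e-06, up). They also were the ERK targets with RA in WT (0.00137, down) and in the interaction (0.00256, up). Without chromosomes 6, 8, 11 and Y, camera called 4, 9 and 7 lists before RA, after RA and for the interaction, against 6, 7 and 9 with them. The germline and Wnt lists lost their call before RA, and the Wnt, imprinted and fibroblast lists in the interaction. The G1-S and mitosis list lost its call with RA in WT, and the mesoderm, imprinted and fibroblast lists with RA in C48S. Calls were gained by the p53 (0.00989) and LIF-STAT3 (0.0408) lists after RA, by the LIF-STAT3 list in the interaction (0.0437) and by the DNA methylation list with RA in WT (0.00528) and in C48S (0.0138). Fry called 16, 21, 25, 22 and 21 of the 25 lists. Of 167 values of 111 named genes, 165 kept their direction and their side of the threshold in all 17 alternatives that gave a value, and Pou5f1 before RA passed (-0.20) without C48S undifferentiated replicate 3. The interaction of Tmem92 passed with 1.96 without C48S undifferentiated replicate 3, 1.19 without WT RA replicate 1 and 1.20 without C48S RA replicate 2, and the cause was not tested. Depth limits the genes near 1 CPM, for which bounds and counting intervals are given.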

Other observations

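The test of Wnt targets without chromosomes 6, 8, 11 and Y and that of calls off these chromosomes were chosen only after the result was seen, and the genes of chromosome Y and of the Dlk1-Dio3 region were picked from their values. At the imprinted Dlk1-Dio3 region of chromosome 12, the noncoding RNAs expressed from the maternal copy were low in C48S in both states. Meg3 was at 75.6 ± 8.76 CPM in WT and 16.7 ± 1.50 CPM in C48S before RA, and at 557 ± 43.6 and 15.1 ± 0.566 CPM after it. Mirg, a microRNA host transcript, was at 98.1 ± 12.8 and 1.54 ± 0.376 CPM after RA, and Rian, which hosts small nucleolar RNAs, at 807 ± 16.2 and 16.4 ± 0.951 CPM. Dlk1, expressed from the paternal copy, rose with RA in C48S to 94.6 ± 4.39 CPM and was at 99.7 ± 3.77 CPM in WT. Before RA it was at 5.59 ± 1.19 CPM in WT and 3.34 ± 0.162 CPM in C48S, and Dio3, another gene expressed from the paternal copy, was at 1.75 ± 0.206 and 6.14 ± 1.39 CPM. After RA Dio3 was at 2.54 ± 0.523 and 1.89 ± 0.285 CPM.

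On chromosome Y the difference between the lines varied from gene to gene. Before RA, the neighbours Zfy1, Uba1y and Kdm5d, between positions 725128 and 956786, were at 24.6 ± 1.39, 60.1 ± 1.45 and 25.0 ± 2.40 CPM in WT and at 0.255 ± 0.225, 1.03 ± 0.182 and 0.409 ± 0.194 CPM in C48S. Farther along, the log2 change was -2.29 for the translation factor gene Eif2s3y, -0.30 for the demethylase-family gene Uty and -1.27 for the helicase gene Ddx3y. The next gene, Usp9y, was at 1.02 ± 0.349 and 0.0345 ± 0.0597 CPM, and Gm47283, far from the others, was higher in C48S (88.7 ± 6.48 and 134 ± 11.5 CPM). C48S undifferentiated replicate 3, which stood apart, had 1.48% of its counts on mitochondrial genes and 1.14% on histone genes, against 1.68 and 1.93% and 0.906 and 0.920% in replicates 1 and 2.

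The shift of chromosomes 6, 8 and 11 may come from a difference in copy number between the lines. If so, genes should be shifted along the whole chromosome, and on each of the 3 chromosomes 100% of windows of 10 Mb lay on the side of its median, in both states. A few strongly changed genes could hardly move a median over 659 to 1167 genes, so leaving them out adds little evidence. Without genes changed by more than 1 on the log2 scale the smallest of the 6 medians was 0.43 in size. RNA gives the difference alone, so which line carries it, and in what share of its cells, stays open, and no biological explanation was tested.

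Before RA, 9970 genes differed between the lines, and chromosomes with a median beyond 0.2 held 23.0% of them. Direct dosage of chromosomes 6, 8, 11 and Y concerns their own genes by definition, so it does not cover the rest. Of the genes elsewhere 52.3% were called, among them 2441 of the 3225 called genes that differed by at least 2-fold. Effects of a copy number change on genes of other chromosomes stay open. Weaker MEK inhibition in the C48S cultures could contribute. Spry4, Etv4 and Etv5 were left out because their values had been seen when the test was set. The 11 other ERK targets had a median of 1.03, with 7 higher and 2 lower. However, the list was also higher in C48S after RA, and the labels do not say whether inhibitors were present then. Weaker GSK3 inhibition cannot be told apart from the chromosome shift, because the Wnt targets had a median of -0.84, whereas the 6 of them off the shifted chromosomes had a median of 0.0459, with 2 higher and 3 lower. The mutation and other properties of the clone stay open as well, untested.

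For each of the 4 comparisons of 2 groups, 10 splits of 6 libraries are too few for a share under 0.05. In edgeR, 1 of 10 splits, the real one, gave 9970 genes before RA, 9785 after RA, 14054 with RA in WT and 13203 with RA in C48S. The highest other split gave 0 in each. Every other split mixed the groups compared, so the difference between them entered its spread. Few or no calls were therefore likely from the start, and the contrast with the real split is no evidence against chance.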
